A study of Arabidopsis thaliana with 6 samples.

How the data were processed

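Messenger RNA was profiled by Illumina sequencing in the entire aerial part of Arabidopsis thaliana plants of the Col-0 accession. Per the labels, plants grew on soil at 22 °C with a 12 h photoperiod and a light intensity of 100 to 120 µmol per square metre per second, and were collected 21 days after germination at zeitgeber time (ZT) 12, the end of the light period. RNA came from an RNeasy plant kit and libraries from standard Illumina protocols, per the labels' protocols. The labels name 3 wild-type libraries and 3 libraries of the quadruple mutant camta1/2/3/sid2.

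The deposited table holds FPKM values (fragments scaled to transcript length and to the mapped fragments of the library), per the file headers, for 33557 loci named by their Arabidopsis locus identifiers. It gives 1 FPKM value per genotype and locus, so the 6 libraries enter only through the authors' combined value for each genotype. How the libraries were combined is not given in the sources used here. TopHat 1.4.1, Cufflinks 2.1.1 and Cuffdiff are named, with the genome build TAIR10, per the submitters' processing notes, which give no version for Cuffdiff. Trimming, strandedness, read length and the treatment of reads that map to several loci are not given in the sources used here.

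FPKM is already scaled for library size and transcript length by the authors, so it is not a count and no count model was used. Depth is unknown. Among 1376 loci above 0 and below 0.1 FPKM in both genotypes, the fullest 0.02-wide bin of the log2 ratio held 1.53%, so the low values show no steps of whole reads from which the relative depth could be read. Summed FPKM was 908640 in the wild type and 891178 in the mutant. The 10 highest loci took 7.48% of that sum in the wild type and 7.31% in the mutant. A value of 0 can be a failed estimate: RBCS1A, which encodes a small subunit of Rubisco, is listed at 0 in both genotypes. Loci at 0 are therefore described only as listed at 0, and no fold is given against them.

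The difference between genotypes was computed as the mutant value minus the wild-type value on the scale of log2(FPKM + 1), called the log2 ratio here. The pseudocount of 1 understates the difference of genes with low values. Folds of FPKM, where printed, are plain ratios without a pseudocount. Loci with an FPKM of at least 1 in at least 1 genotype were analysed, which left 18547, of which 17765 are annotated as protein coding. Loci at or beyond a 2-fold difference on this scale were counted. With 1 value per genotype there is no replicate check, so no p-value, standard deviation or replicate number is given for any difference.

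For 24 gene lists, the median log2 ratio over the analysed members was set against 10000 random lists of the same size, drawn from the same 20 bins of mean expression. Its percentile among them describes these values and is not a test of the genotypes. Random lists treat genes as independent, while co-regulated genes move together, so a list falls outside the central 95% more easily than the random lists imply. Lists with fewer than 3 analysed members have no percentile.

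The gene lists, the rule for named genes, the filter, the pseudocount, the 2-fold threshold and the switch to ratios without a test for a table with 1 value per genotype were fixed before the data were examined. The rule names every targeted gene and the other CAMTA genes; CBP60g, SARD1, EDS5, PBS3, PAD4, EDS1, PR1, PR2, PR5, CBF1, CBF2 and CBF3 whatever their values; the 10 highest and 10 lowest log2 ratios with an FPKM of at least 5 in the higher genotype; and up to 4 analysed members of each list with the highest absolute log2 ratio. Genes named outside this rule are said to have been chosen after their values were seen, and list members cited beyond the rule serve as examples of their list. Alternatives planned in advance were pseudocounts of 0.1 and 0.5, no filter on low values, a filter of 5 FPKM, and ratios scaled to a median of 0. Leaving out loci listed at 0 in either genotype, and keeping protein-coding loci of the nuclear genome only, were added after seeing the data.

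Symbols, gene types, transcript length, GC content and upstream sequence came from the RefSeq annotation of the TAIR10.1 assembly, joined by locus identifier. Of the 33557 loci, 32813 (97.8%) matched. Because the authors' build is named TAIR10, no coordinates are printed. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9.

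The procedure was tested on simulated data for the comparison of camta1/2/3/sid2 with the wild type, over 18547 genes of which 200 were given a known difference. It counted as 2-fold 83.7% of genes with a true log2 difference of -2, 80.0% at -1.5, 98.1% at 1.5 and 100% at 2, and 0 of the other genes. Of 200 simulated lists of 15 genes without a difference, 3.5% fell outside the central 95%, and 100% of 100 lists shifted by 0.5 lay above it. The simulated SD of the log2 ratio was an assumed 0.141, because the table holds no replicates. With so small a spread unchanged genes could hardly reach 2-fold, and no loci at 0 were simulated. The count of 0 other genes therefore does not estimate false calls in these data. The simulated lists were drawn at random from independent genes, so the 3.5% does not describe lists of co-regulated genes. The 100% holds only for a shift of 0.5 at the assumed spread, and several list medians below are smaller than that shift.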

Results

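The data compare the transcriptome of camta1/2/3/sid2 plants with that of wild-type Arabidopsis grown in warm soil conditions and collected at dusk. CAMTA1, CAMTA2 and CAMTA3 are calmodulin-binding transcription factors that restrain salicylic acid immunity at warm temperature and take part in the induction of cold-response genes. SID2 encodes isochorismate synthase 1 (ICS1), the main source of salicylic acid in immune responses. The comparison addresses which messenger RNA levels differ from the wild type when these 3 factors and this route to salicylic acid are disrupted together. A single sid2 mutant and a camta mutant with functional ICS1 are not analysed here, so the contributions of the mutated genes are not separated. Each genotype has 1 FPKM value per locus, combined by the authors from 3 libraries, and no difference below has a replicate check.

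The targeted transcripts were lower in the mutant to different degrees. CAMTA1 (AT5G09410) stood at 13.6 FPKM in the wild type and 3.30 in the mutant, which is 4.13-fold lower. CAMTA3 (AT2G22300) was 3.72-fold lower, at 9.94 against 2.68 FPKM. CAMTA2 (AT5G64220) was 9.25 in the wild type and 6.32 in the mutant, and ICS1/SID2 (AT1G74710) was 4.56 and 3.73. The remaining family members differed little: CAMTA4 (AT1G67310) was 11.3 and 10.5 FPKM, CAMTA5 (AT4G16150) 13.9 and 12.8, and CAMTA6 (AT3G16940) 13.6 and 12.5. All 4 targeted genes were lower, with a median log2 ratio of -1.03, at percentile 0.02 of random lists. The labels name no alleles, so the levels of CAMTA2 and ICS1 could not be checked against the position of a mutation, and they do not check the labels.

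Most of the transcriptome was close between the genotypes. Of 18547 analysed loci, 96.2% lay within 1.5-fold on the log2(FPKM + 1) scale, and the median log2 ratio was -0.06, with the 5th percentile at -0.38 and the 95th at 0.33. Since this median lay below 0, most analysed loci were slightly lower in the mutant. Counts of lower list or family members are therefore to be read together with the percentiles. Pearson's r of log2(FPKM + 1) was 0.981 across genes, which are not independent replicates. There were 146 loci at least 2-fold higher and 128 at least 2-fold lower in the mutant. Of these, 37 of the higher loci were listed at 0 in the wild type and 46 of the lower loci at 0 in the mutant, which leaves 109 higher and 82 lower above 0 in both. With a pseudocount of 0.1 the counts were 206 higher and 205 lower, and at 5 FPKM or more they were 91 and 91.

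**Figure D1:**
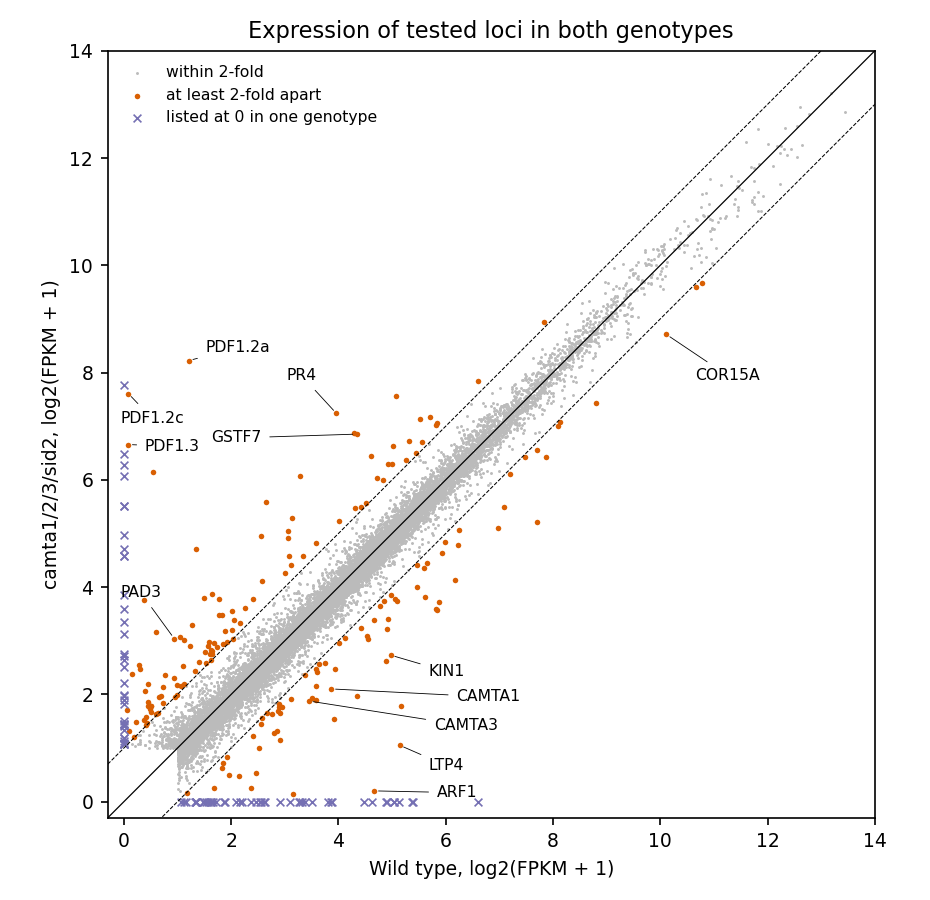
Expression of the analysed loci in the wild type (x axis) and camta1/2/3/sid2 (y axis), both as log2(FPKM + 1), with 1 point per locus; the solid line marks equality and the dashed lines a 2-fold difference. Most points lie near the solid line, and the defensin genes PDF1.2a, PDF1.2c and PDF1.3 stand far above it, while the 83 crosses on the axes are loci listed at 0 in 1 genotype.

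The 10 highest and 10 lowest log2 ratios divided into defensins and loci listed at 0 in 1 genotype. On the higher side stood 4 plant defensin genes, small antimicrobial proteins used as markers of ethylene and jasmonate signalling. PDF1.2a (AT5G44420) was 1.32 FPKM in the wild type and 298 in the mutant, a log2 ratio of 7.01. PDF1.2b (AT2G26020) was 0.454 and 69.9, PDF1.2c (AT5G44430) 0.0604 and 194, and PDF1.3 (AT2G26010) 0.0595 and 100.04 FPKM. These copies are near-identical, so their individual values depend on how shared reads were divided. The other 6 of the highest were listed at 0 in the wild type, among them the microRNA locus MIR160c at 88.6 FPKM in the mutant and the chloroplast locus ATCG00110 at 216. All 10 of the lowest were listed at 0 in the mutant, and only 2 of them, AT3G29633 and AT1G61165, are annotated as protein coding. MIR825, for example, was at 32.0 FPKM in the wild type.

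Salicylic acid responsive genes were lower in the mutant as a group. Of 18 analysed members, 16 were lower and 2 higher, with a median log2 ratio of -0.65, at percentile 0 of random lists. WRKY38 (AT5G22570), a transcription factor induced by salicylic acid, was 4.14 FPKM in the wild type and 0.198 in the mutant. AZI1 (AT4G12470), a lipid-transfer-like protein of systemic immunity, was 14.3 and 4.53, and NIMIN1 (AT1G02450), an interactor of the salicylic acid receptor NPR1, was 4.92 and 1.97. The pathogenesis-related gene PR2 (AT3G57260) was 10.7 and 5.38 FPKM, and PR5 (AT1G75040), at 17.8 FPKM in the wild type, was 1.62-fold lower in the mutant. PR1 (AT2G14610) was under the filter in both genotypes, at 0.909 and 0.477. WRKY70 (AT3G56400), a regulator between salicylic acid and jasmonate responses, was 96.6 and 52.0. PNP-A (AT2G18660), a secreted natriuretic-like peptide, went the other way, from 1.41 FPKM in the wild type to 8.87 in the mutant.

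The genes that make salicylic acid or control its synthesis did not share that direction. Of 18 analysed members, 9 were higher and 9 lower. The transcription factor CBP60g (AT5G26920) was 1.75 FPKM in the wild type and 3.36 in the mutant, while SARD1 (AT1G73805), its close relative, was 1.05-fold higher in the mutant, at 5.23. EDS5 (AT4G39030), the salicylic acid pathway transporter, was 3.24 and 5.10, and PBS3 (AT5G13320), which conjugates isochorismate, was 2.01-fold higher from 1.09 in the wild type. FMO1 (AT1G19250), the enzyme that makes the immune signal N-hydroxypipecolic acid, was 0.0453 and 2.27, whereas ICS2 (AT1G18870), the ICS1 paralogue, was 3.37 and 1.70. PAD4 (AT3G52430) was 8.45 and 9.21 and EDS1 (AT3G48090), its partner in immune signalling, 11.1 and 9.67. The median log2 ratio of the list was -0.03 and its mean 0.09, at percentile 85.2; without the filter on low values the median was 0.028, at percentile 98.4.

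The jasmonate and ethylene list went both ways, and the examples other than ORA59 and PR4 were picked after seeing the values. ORA59 (AT1G06160), the transcription factor that activates the defensins, was 0.419 FPKM in the wild type and 2.43 in the mutant. PR4 (AT3G04720), a chitin-binding protein, was 10.3-fold higher, at 14.6 and 150, and the basic chitinase PR3 (AT3G12500) was 1.37 and 3.00. The vegetative storage protein genes were lower, VSP1 (AT5G24780) at 74.0 and 45.5 FPKM and VSP2 (AT5G24770) at 86.1 and 59.2. Jasmonate biosynthesis genes such as LOX2 (AT3G45140), at 630 and 612, and AOS (AT5G42650), at 171 and 164, were close between genotypes. The JAZ repressor genes of jasmonate signalling went both ways, with log2 ratios of 0.49 for JAZ9 (AT1G70700), 0.36 for JAZ6 (AT1G72450), -0.11 for JAZ2 (AT1G74950) and -0.19 for JAZ10 (AT5G13220). ERF1 (AT3G23240), another activator of the defensins, was under the filter, at 0.151 and 0.216. Across the list 12 of 21 members were higher, with a median of 0.07, at percentile 99.1. Among members with at least 5 FPKM the median was -0.041, at percentile 51.0.

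The camalexin genes were the list with the highest median. PAD3 (AT3G26830), which catalyses the last step to this antimicrobial indole compound, was 0.919 FPKM in the wild type and 7.22 in the mutant. CYP71A13 (AT2G30770) was 0.649 and 3.39, and its close copy CYP71A12 (AT2G30750) was 0.369 and 2.44. All 3 were at least 2-fold higher, with a median log2 ratio of 1.41, at percentile 100; these low values gave a median of 2.44, at percentile 99.97, with a pseudocount of 0.1, and the filter of 5 FPKM left too few members for a median. The glucosinolate list, another set of indole and aliphatic defence compounds, was lower in 17 of 20 members by small amounts, with a median of -0.16, at percentile 0.28. The myrosinases TGG1 (AT5G26000), at 1937 and 1594 FPKM, and TGG2 (AT5G25980), at 1024 and 781, were among them, while the regulator MYB51 (AT1G18570) was 5.58 and 9.67.

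Other immune genes showed smaller differences. Of 17 pattern-triggered immunity genes, 6 were higher and 11 lower, with a median of -0.14, at percentile 4.91; with a pseudocount of 0.1 it was -0.20, at percentile 1.46. CYP81F2 (AT5G57220), an enzyme of indole glucosinolate modification, stood apart at 0.368 FPKM in the wild type and 2.63 in the mutant, while the chitin receptor LYK5 (AT2G33580) was 4.11 and 2.27. All 20 analysed NLR receptor genes lay within 1.5-fold on the log2(FPKM + 1) scale, with a median of -0.04, at percentile 73.8. CHS1 (AT1G17610) was 3.77 and 5.81 FPKM, and ZAR1 (AT3G50950) was 48.5 and 36.6.

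The rapid stress response list and the list of calcium-related genes had higher medians in the mutant, with clear exceptions. TCH3 (AT2G41100), a calmodulin-like protein that belongs to both lists, was 29.2 FPKM in the wild type and 77.9 in the mutant. The zinc finger gene ZAT10 (AT1G27730), at 4.64 in the wild type, was 1.83-fold higher, and ERF104 (AT5G61600), an ethylene-response factor, was 2.83 and 5.41. TCH4 (AT5G57560), a cell wall enzyme induced by touch, was 6.98 and 3.10. Among calmodulin-like genes, CML46 (AT5G39670) was 2.81 and 6.92 FPKM, whereas CML24 (AT5G37770) was 24.3 and 9.41. Of 12 rapid stress genes 9 were higher, with a median of 0.38, at percentile 100. Of 8 analysed calcium-related genes 5 were higher, with a median of 0.47, at percentile 100. All 8 are calmodulin-like genes, since the calcium pumps ACA12 and ACA13 were under the filter. Genes that share the symbol CAM, a family looked at after seeing the values, were lower in 7 of 8. Their median was -0.17, at percentile 1.71.

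**Figure D2:**
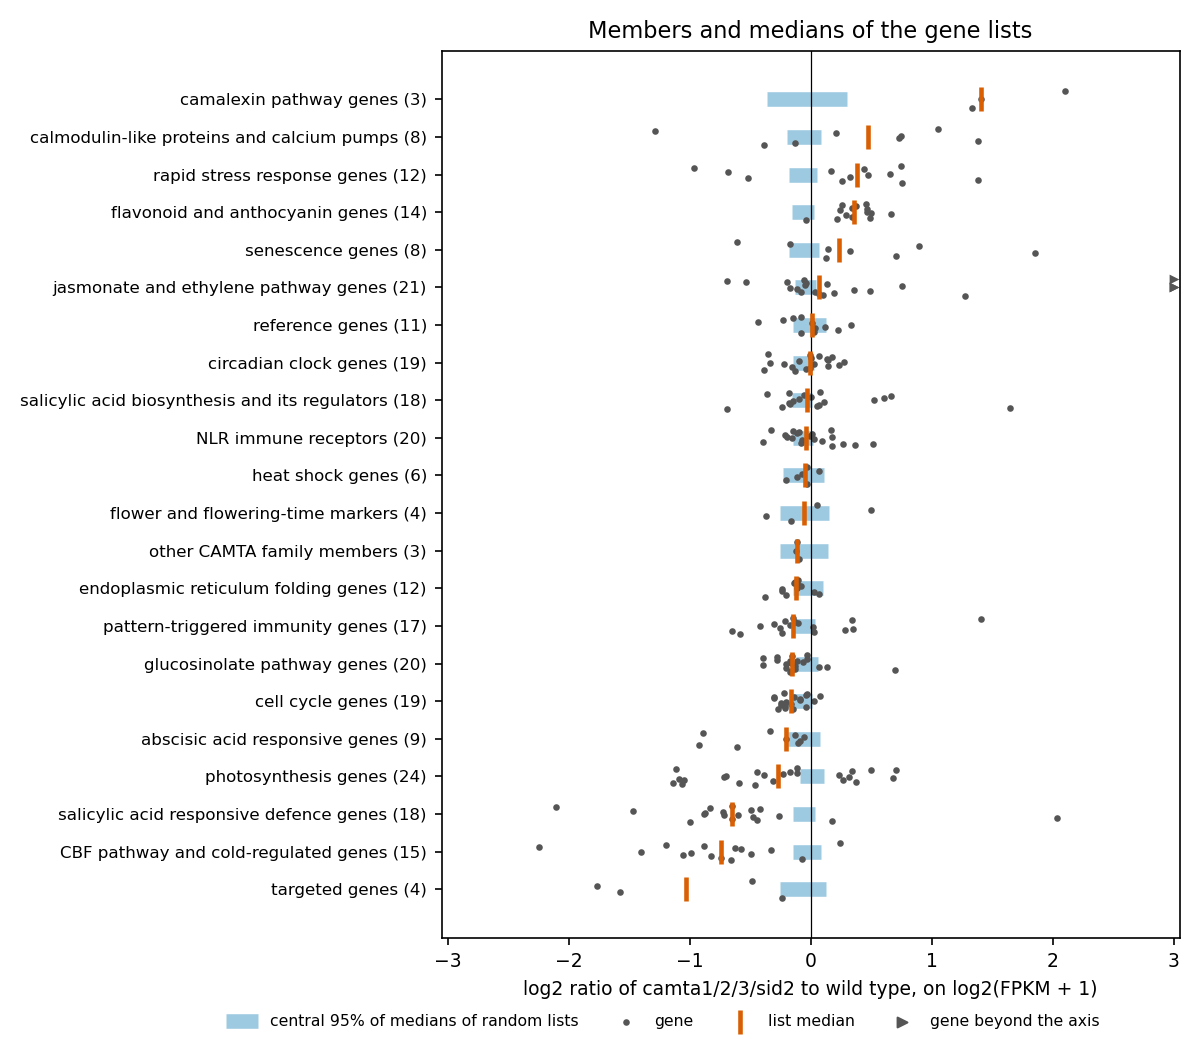
Log2 ratio of camta1/2/3/sid2 to the wild type on log2(FPKM + 1) for the analysed members (points) of each gene list with at least 3 of them, with the list median (orange line) and the central 95% of medians of 10000 random lists (blue band). The medians of the camalexin list, at 1.41, and the cold-regulated list, at -0.74, lie outside their bands on opposite sides.

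Most analysed cold-regulated genes of the list were lower in the mutant although no plant was chilled. COR15A (AT2G42540), a protein that protects chloroplast membranes during freezing, was 1108 FPKM in the wild type and 418 in the mutant. RD29A (AT5G52310) was 75.5 and 32.3, COR414-TM1 (AT1G29395) 278 and 133, and KIN1 (AT5G15960) 30.5 and 5.64. KIN1 has a near-identical neighbour, KIN2 (AT5G15970), at 3779 and 2056 FPKM, and how reads shared by both were divided is not given. Of the CBF genes that encode activators of cold-regulated genes, CBF3 (AT4G25480) was 8.55 and 5.18. CBF1 (AT4G25490), at 0.493 and 0.233, and CBF2 (AT4G25470), at 0.133 and 0.138, were under the filter. Other members did not share the large differences. ZAT12 (AT5G59820) was higher, at 1.14 and 1.53, RAV1 (AT1G13260) was 4.27 and 4.01, and HSFC1 (AT3G24520) was 4.35 and 3.26. Of 15 analysed members 14 were lower, 4 of them at least 2-fold, with a median log2 ratio of -0.74, at percentile 0.

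Abscisic acid responsive genes were lower in 9 of 9 analysed members. NCED3 (AT3G14440), the key enzyme of abscisic acid synthesis under drought, was 2.36 FPKM in the wild type and 0.780 in the mutant. The phosphatase genes HAI1 (AT5G59220), at 6.53 and 3.06, and HAI2 (AT1G07430), at 1.72 and 0.786, and the dehydrin RAB18 (AT5G66400), at 13.6 and 10.6, had the next differences in size. The median was -0.20, at percentile 1.61, and it did not stay below the central 95% under several settings, with -0.13 at percentile 19.1 among members with at least 5 FPKM.

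The photosynthesis list went both ways. All 14 light-harvesting antenna genes of the list were lower, with a median log2 ratio of -0.64, at percentile 0, while LHCB4.3 (AT2G40100), an antenna gene outside the list, was higher, at 51.3 and 143 FPKM, and LHCB2.3 (AT3G27690), another, was lower, at 62.6 and 27.7. LHCB3 (AT5G54270) was 1760 FPKM in the wild type and 815 in the mutant, LHCB1.2 (AT1G29910) 1623 and 775, LHCB1.1 (AT1G29920) 207 and 93.7, and LHCB2.1 (AT2G05100) 146 and 68.3. The LHCB1 and LHCB2 copies are near-identical and can share reads, but the 9 antenna genes of the list outside both were also lower, with a median of -0.45. The 6 carbon fixation genes of the list were higher, with a median of 0.44, at percentile 100: RBCS2B (AT5G38420), a Rubisco small subunit, was 3096 and 5063, and Rubisco activase RCA (AT2G39730) was 1944 and 3121. The copies RBCS1B, RBCS2B and RBCS3B can share reads as well, and RBCS1A is listed at 0 in both genotypes. RCA, GAPA1 and GAPB, which are not RBCS copies, were also higher. The remaining members, photosystem subunits, were mixed, with log2 ratios of -0.11 for PSAD1 (AT4G02770), -0.12 for PSBO1 (AT5G66570), 0.24 for PSBO2 (AT3G50820) and 0.26 for PSBR (AT1G79040). The split into antenna and carbon fixation genes was made after seeing the values, so the percentiles of these subsets are not independent of their direction. As fixed in advance, the list had 8 of 24 members higher and 16 lower, with a median of -0.27, at percentile 0. Summed FPKM of chloroplast-encoded loci was 6250 in the wild type and 8482 in the mutant.

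The circadian clock list had a median of 0.00, at percentile 89.5, with 9 of 19 members higher. Its largest differences were in genes expressed during the day: GI (AT1G22770) was 19.7 FPKM in the wild type and 14.9 in the mutant, LNK1 (AT5G64170) 8.04 and 6.09, and PRR7 (AT5G02810) 12.8 and 9.92. RVE4 (AT5G02840), a morning-class activator, was 21.3 and 26.0.

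Flavonoid and anthocyanin genes were higher in 13 of 14 analysed members, each by less than 2-fold. UGT75C1 (AT4G14090), an anthocyanin glucosyltransferase, was 8.34 FPKM in the wild type and 13.8 in the mutant, LDOX (AT4G22880) 14.9 and 21.5, and F3H (AT3G51240) 11.3 and 16.3. Chalcone synthase CHS (AT5G13930), the entry enzyme, was 100.1 and 138. The median was 0.36, at percentile 100. Senescence genes were higher in 6 of 8 members, with a median of 0.23, at percentile 99.98. SAG21 (AT4G02380), a late-embryogenesis-like protein also induced by oxidative stress, was 7.35 and 29.1 FPKM, SEN1 (AT4G35770) 5.85 and 11.8, and SAG13 (AT2G29350) 5.48 and 9.60, while SAG14 (AT5G20230) was 19.4 and 12.4.

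**Figure D3:**
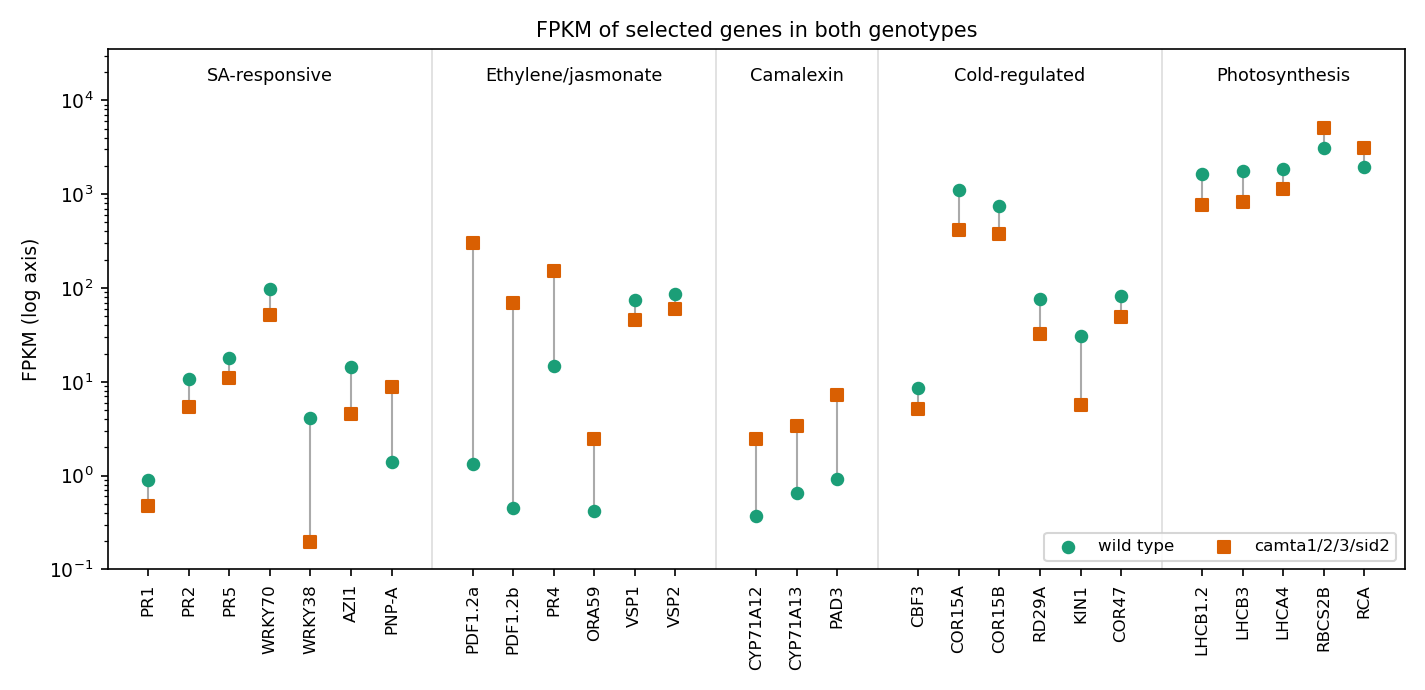
FPKM (log axis) of selected genes in the wild type (circles) and camta1/2/3/sid2 (squares), grouped by process, with 1 value per genotype and no error bars. PDF1.2a stands at 1.32 and 298 FPKM and COR15A at 1108 and 418, while LHCB3 and RCA differ in opposite directions.

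Cell cycle genes were slightly lower, in 17 of 19 members, with a median of -0.16, at percentile 1.12. CDKB1;1 (AT3G54180), a mitotic kinase, was 13.4 FPKM in the wild type and 10.6 in the mutant, and the replication factor PCNA1 (AT1G07370) was 27.6 and 22.7. Of the shoot meristem markers, STM (AT1G62360) was 4.67 and 2.37, and CLV1 (AT1G75820), at 16.2 in the mutant, was 1.12-fold lower. Endoplasmic reticulum folding genes were lower in 10 of 12 members, with a median of -0.12, at percentile 5.99. CRT3 (AT1G08450), a calreticulin, was 38.1 and 29.1. Heat shock genes had a median of -0.05, at percentile 62.0, with HSFA2 (AT2G26150) at 3.55 and 2.94 FPKM. Flowering-time and flower markers had a median of -0.06 and a mean of 0.01, at percentile 53.5, with the repressor FLC (AT5G10140) at 4.73 and 7.10 and the activator SOC1 (AT2G45660) at 19.0 and 14.5. Root markers were represented by PYK10 (AT3G09260), at 51.6 and 55.8, and CASP1 (AT2G36100), at 0.940 and 1.57.

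Reference genes used for normalising transcript levels gave the background of the comparison. Of 11, 6 were higher and 5 lower, all within 1.5-fold on the log2(FPKM + 1) scale, with a median of 0.02 and a mean of -0.02, at percentile 70.1. ACT2 (AT3G18780) was 309 FPKM in the wild type and 390 in the mutant, and UBC9 (AT4G27960) was 168 and 124. Of the 22 lists with a percentile, 13 lay outside the central 95% of random lists, 6 above and 7 below, where 1.1 would be reached by chance among independent genes. The 7 below include the targeted genes, which the mutations themselves can lower. Among the 6 above, the rapid stress and calcium-related lists share TCH3. When ratios were scaled to a median of 0, the medians of the salicylic acid biosynthesis, NLR, clock, heat shock and flowering lists, which all lay within 0.06 below 0, turned positive.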

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

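All results come from 1 value per genotype, and the depth behind each is unknown, so low values are the least secure. Leaving out loci at 0 and keeping protein-coding nuclear loci only were chosen after seeing the data. Lowering the pseudocount to 0.1 gave 205 loci at least 2-fold lower in place of 128, brought the pattern-triggered immunity median to -0.20 (percentile 1.46) and the abscisic acid median to -0.22 (percentile 2.54, just inside the central 95%). Without a filter, the salicylic acid biosynthesis median was 0.028 (percentile 98.4, from -0.03) and the abscisic acid median -0.17 (percentile 2.5). At 5 FPKM or more, where 13936 loci were tested, 91 were at least 2-fold higher, the jasmonate and ethylene median was -0.041 (percentile 51.0, from 0.07) and the abscisic acid median -0.13 (percentile 19.1); low members such as ORA59 and PR3 drop out there by construction. Without loci at 0, 82 were at least 2-fold lower, and among protein-coding nuclear loci 85. Other causes were not tested. The camalexin median was 2.44 (percentile 99.97) at a pseudocount of 0.1, the senescence median 0.13 (percentile 99.96) without a filter, and at 5 FPKM or more the targeted median was -1.57 (percentile 0) and the calcium-related median 0.73 (percentile 99.985). The camalexin, heat shock and flowering lists had too few members at 5 FPKM for a median, and ICS1 was under that filter. No list moved from below the central 95% to above it, or back, under these settings. With a pseudocount of 0.5 the counts were 169 higher and 156 lower, and after scaling to a median of 0 they were 158 and 121. For named genes, 34 log2 ratios differed by more than 1.5-fold at a pseudocount of 0.1 and 24 at 0.5.

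No paired analysis was possible because the table holds 1 value per genotype and carries no replicate numbers. For the same reason the tests planned for values per library were not run: leaving out each replicate, the replicate block, quantile normalisation, the fit without an intensity trend, and the gene set tests with an estimated correlation or with fry.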

Other observations

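The gene families in this part, the single genes in its second paragraph, and the tests on defensins, on antenna copies and evening timing, and on loci at 0 were chosen after the values were seen. The GC and length test and the tests of the CAMTA recognition motif were written before their results were seen. As written, the motif tests covered all genes 2-fold apart. Their limit to protein-coding genes above 0 in both genotypes was not part of that. Among 175 families of genes that share a symbol and have at least 8 analysed members, 18 had a median above the central 95% of random lists and 16 one below it, where 4.4 per side would be reached by chance among independent genes. Those below were of mixed kinds. They included the symbols PRA, lower in 13 of 15, RAB in 10 of 11, MCM in 8 of 8, UMAMIT in 22 of 27 and TPR in 15 of 15. The families described next are a selection. Of 24 arabinogalactan proteins (AGP), cell surface glycoproteins, 19 were lower in the mutant, with a median log2 ratio of -0.35, AGP9 at 664 FPKM in the wild type and 405 in the mutant and AGP19 at 47.7 and 19.4. The related fasciclin-like proteins (FLA) were lower in 11 of 13, at percentile 0.1. The IRX genes of secondary wall synthesis were lower in 10 of 10, with a median of -0.24, at percentile 0.36. The IRX genes include the cellulose synthases IRX1, at 5.07 and 3.54 FPKM, and IRX3, at 3.65 and 2.80. Of other families with members in cell wall metabolism, the expansins (EXPA) were lower in 8 of 12, at percentile 1.36. Inside the central 95% lay XTH at percentile 7.56, GAUT at 9.48, GSL at 26.6, BGAL at 26.7 and TBL at 37.0. All members of GAUT, 12 of 12, and of GSL, 8 of 8, were lower too, so such counts alone do not set a family apart. On the higher side, 7 of 9 phi-class glutathione transferases (GSTF) were higher, with GSTF6 at 44.8 and 139.9 FPKM and its close neighbour GSTF7 at 19.3 and 114.6. Only these 2 were at least 2-fold higher, and how any reads shared by both were divided is not given. GSTF8 and GSTF9, counted as higher, were close between genotypes, with log2 ratios of 0.014 and 0.042. Methionine sulfoxide reductases (MSRB), which repair oxidised methionine, were higher in 8 of 8. Nuclear genes named for chloroplast electron transport phenotypes were higher as well, CRR in 10 of 11, with CRR6 at 67.8 and 100.1 FPKM, and HCF in 11 of 12, with HCF173 at 32.6 and 50.1. In the methylesterase family (MES), MES8, at 3.51 and 9.08 FPKM, MES18, at 18.7 and 43.6, and MES16, with a log2 ratio of 1.27, were at least 2-fold higher.

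Among protein-coding genes above 0 in both genotypes, a few stood far below the wild type outside the gene lists. The lipid transfer protein genes LTP4 and LTP3, neighbouring copies, were at 34.4 and 34.8 FPKM in the wild type and at 1.07 and 2.45 in the mutant. The auxin response factor gene ARF1 (AT1G59750) was 24.5 and 0.151, and GUS2, a glucuronidase gene, 7.92 and 0.104; whether these values near 0 come from an insertion, a gene-model problem or a failed estimate was not tested. The orphan gene QQS was 70.8 and 16.6, and AT5G03350 was 206 and 36.0. LHCB4.3, a stress-associated antenna gene outside the fixed list, was 51.3 and 143, against the direction of the antenna genes in the list.

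Protein-coding genes above 0 in both genotypes and at least 2-fold lower carried the CAMTA recognition motif upstream more often than chance sets. The hypothesis written beforehand was that genes 2-fold apart more often have vCGCGb (v is A, C or G, and b is C, G or T) within 1000 bp upstream. It named all such genes, whereas the test kept only protein-coding genes above 0 in both genotypes. Among 68 such lower genes, 21 (30.9%) had it, at the 98.7th percentile of expression-matched sets with a median of 19.1%, while the rearranged control vGCGCb lay at the 71.8th. Among 84 such higher genes, 14 (16.7%) had vCGCGb, at the 19.5th percentile, and the control vGCGCb lay at the 9.4th. The motif was thus not more frequent in the higher genes than in random sets. Since the control was low there too, no more is drawn from this value. A further motif, CGCGTT, was found in 13 of the 68 lower genes (19.1%), at the 99.7th percentile. It was found in 8 of the 84 higher genes (9.5%), at the 55th. CGCGTT shares CGCG with vCGCGb, so it is not a separate check. The lower genes may include some that need CAMTA factors for activation. That is a hypothesis only, since binding was not measured and the sid2 mutation is in the same plants. CML24, WRKY38, EXLA1 and AGP19 are lower genes with the motif vCGCGb, though sid2 by itself could lower a salicylic acid responsive gene such as WRKY38.

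The defensins PDF1.2a, PDF1.2b, PDF1.2c and PDF1.3 were higher in the mutant by more than any other protein-coding gene above 0 in both genotypes. Reads moved among near-identical copies would leave their total in place, but all of these copies were higher in the mutant. The summed FPKM of 6 PDF1 genes was 21.7 in the wild type and 679 in the mutant, 31.3-fold higher. That sum includes PDF1.5, outside the copies named above, at 19.0 and 16.4 FPKM. PDF1.5 makes up most of the wild-type sum, so the 31.3-fold is not the difference of the copies. A general immune activation, such as by a pest on the mutant plants, cannot be told apart from a genotype effect: the pattern-triggered immunity list lay inside the central 95%, at percentile 4.91, and ranged from percentile 1.46 with a pseudocount of 0.1 to percentile 28.1 at 5 FPKM or more. The salicylic acid responsive list, at percentile 0, decides nothing here, because sid2 by itself can lower it. A weaker salicylic acid response that goes with a stronger ethylene and jasmonate response also stays open: 3 of 3 genes among ORA59, PR3 and PR4 were higher, but they had been seen as higher beforehand, and ERF1, at 0.151 and 0.216 FPKM, was low in both, so these values decide nothing.

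The light-harvesting antenna genes of the fixed list were lower in 14 of 14 cases, while outside the list LHCB4.3 was higher and LHCB2.3 lower, at 62.6 and 27.7 FPKM. A trend of all loci with GC content or transcript length is argued against as the whole cause, since it was small: removing it shifted the 17774 loci by between -0.086 and 0.089 and kept 100.4% of the antenna median. Reads shared by LHCB1 and LHCB2 copies do not bear on the 9 antenna genes of the list outside both subfamilies, which were lower with a median of -0.45. That 9 of 9 were lower was already known when this check was written. It says nothing about the size of the difference in the LHCB1 and LHCB2 copies themselves. A later point of the evening at harvest of the mutant cannot be told apart from a genotype effect: of PRR5, PRR7, GI, LNK1 and FKF1, which decline around dusk, 3 of 5 were lower by at least 0.3, while PRR5 was higher, with a log2 ratio of 0.14, and FKF1 was close, at 22.7 and 22.1 FPKM, as was the evening gene TOC1, at 57.7 and 57.4. An effect of genotype on these genes may remain, untested for want of other time points.

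Of the analysed loci, 83 were listed at 0 in 1 genotype, some with high values in the other. If these are unstable estimates of short or non-coding loci, such loci should be over-represented, and 59.0% of the 83 are not annotated as protein coding, against 3.97% of the loci above 0 in both, a ratio of 14.9. The zeros are thus consistent with failed or unstable estimates. A biological difference at single loci such as MIR160c or MIR825 was not tested.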
